A study of Rattus norvegicus with 3 samples.

How the data were processed

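Chromatin immunoprecipitation with sequencing (ChIP-seq) of the glucocorticoid receptor (GR) was carried out on neonatal rat ventricular myocytes, heart muscle cells isolated from Sprague Dawley pups and enriched over non-myocytes by density gradient and preplating, per the labels' protocols. 1 GR library came from cells given ethanol, the vehicle, and 1 from cells given 100 nM dexamethasone (Dex), a synthetic glucocorticoid, for 1 h. Another library was input DNA without antibody. Groups were taken from the sample titles. With 1 library per group there are no replicates, so no p-value, standard deviation or standard error is given, and each difference compares 2 libraries and not the conditions.

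Reads were mapped with BWA to the rat build rn5, per the submitters' processing notes, which give no version. The ChIP, library preparation and sequencing were done by a contract laboratory, per the labels' protocols. The peak caller, its threshold, the use made of the input library, the scaling of the libraries to each other and the gene annotation used are not given in the sources used here. Per the file headers, each region holds 1 or more intervals, and the authors recorded whether it was present in (here, called in) each GR library. The deposited signal values of a region are an average and a peak value in each library, called heights here. Peak heights were whole numbers, and they were treated as signal of unknown scaling and not as read counts. The deposited tables hold no total counts, so the depth of the libraries is unknown, and no interval is given on the height of a single region. Intervals on heights or log2 ratios over sets of regions cover the spread among regions only, not depth or scaling. No height of the input library was among the columns, so leaving out regions of high input was not tried. 0 columns belonged to samples outside the 3 listed.

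The region table held 11658 regions numbered without a gap, on 20 autosomes and X. The gene table held 7080 genes, each with at least 1 region, and its number of regions per gene equalled that in the region table for 100% of genes. The authors' mean Dex height per gene lay within 1 of the mean computed here for 100% of genes. Distances to a gene start run from the middle of the region, and a negative distance is upstream. Upstream assignments reached 10401 bp. The authors' promoter count was matched by a range from 7500 bp upstream to 2500 bp downstream of the start for 99.5% of regions. The table says whether a region lies in, upstream or downstream of a gene and whether it overlaps a CpG island, not whether it lies in an exon, an intron or a UTR. Coordinates are those of the files, on rn5. Whether they count from 0 or 1 is not stated there.

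The ratio of a region is (Dex peak height + 1) / (control peak height + 1), and the log2 ratio is its base 2 logarithm. The added 1 understates the change where the control height is low. Ratios, before the logarithm, of 2 or more and of 0.5 or less were counted. A region with several genes was placed by the gene whose start was nearest. Shares of regions have exact Clopper-Pearson 95% intervals, which cover counting error only. 17 gene lists were fixed before the data were examined. Members were joined to the gene table by NCBI gene ID through a reference table of rat gene names for the assembly GRCr8, used for names only, which held 6823 of the 7080 IDs. A gene's height is that of its assigned region with the highest Dex peak. The median height of a list with 3 or more listed members was placed as a percentile among 10000 random lists of the same size drawn from the gene table within 10 classes of gene length. That percentile describes these libraries and is not a p-value. The number of members listed was placed likewise among 10000 random lists from the 18539 protein-coding genes of the name table with a curated transcript, of which 34.7% were listed. That comparison was not matched on gene length and was chosen after the data were seen.

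Named genes followed a rule fixed before the data were examined. They are the nearest gene of the 12 regions with an assigned gene and the highest Dex peak height at a ratio of 4 or more, of the 5 control-called regions with the highest control height, and of up to 5 control-called regions with the lowest ratio at 0.5 or less. All members of the list of canonical GR targets are covered, and up to 4 members of each other list by Dex height. Some genes that the rule takes are not reported here. Regions named outside the rule are said to be chosen after their values were seen. Alternatives covered the threshold of a call, the height used, the pseudocount, the scaling, filters and the assignment to genes. The planned search for GR response elements was not run because no rn5 sequence was used here. On simulated data for the gene lists, 100% of 100 lists of 20 genes with heights doubled by design (a simulated fold of 2) reached the 95th percentile among 7080 genes, as did 5% of lists of unchanged genes. All members of a list were changed together, and simulated heights had no link to gene length. Most lists here had fewer listed members, and shorter or partly changed lists were not simulated. For the region signal, Poisson counts were drawn around each region's control height plus 5, with no difference in scaling between the libraries. In that simulation 100% of 200 regions at a fold of 8 among 11658 passed the ratio of 2, as did 6.14% of unchanged regions. The real heights are of unknown scaling and the simulated levels lay above the control heights, so the 6.14% is not an error rate for these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.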

Results

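Genomic binding of GR was profiled in neonatal rat ventricular myocytes after 1 h of 100 nM dexamethasone and after ethanol. The deposited tables give 11658 regions in which GR signal was called in at least 1 of the GR libraries, with the peak height of each library in each region. The median region was 327 bp long (quartiles 251 and 455 bp). There was 1 library per group, so no difference below has a replicate check. The depth and the scaling of the libraries are unknown.

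The question addressed by the main comparison is where GR binds the cardiomyocyte genome once its ligand is added. Nearly all calls were in the Dex library. Of the 11658 regions, 11656 were called in Dex and 30 in control, with 28 called in both and 2 in control alone. The median peak height was 27 in Dex (quartiles 21 and 37, highest 410) and 5 in control (quartiles 4 and 8). Peak height was greater in Dex in 11649 regions, equal in 3 and lower in 6. At a ratio of 2 or more stood 10894 regions (93.4%, exact 95% interval of counting error 93.0 to 93.9%), and 1 region stood at 0.5 or less. The median log2 ratio was 2.17 (quartiles 1.54 and 2.95). Nearly all regions entered the table through a Dex call, which by itself favours a greater Dex height. These shares and ratios therefore describe the called regions and not the genome. Centring the log2 ratios on the 28 regions called in both shifts all of them by 0.72 and leaves 7957 regions at a ratio of 2 or more. Centring on regions with a CpG island, an alternative chosen after the data were seen, shifts the log2 ratios by 1.52. It leaves 4469 regions at a ratio of 2 or more and puts 115 at 0.5 or less. The 30 control calls do not cover all control signal, since 280 regions had a control height at or above 15, the lowest height of any region called there.

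**Figure D1:**
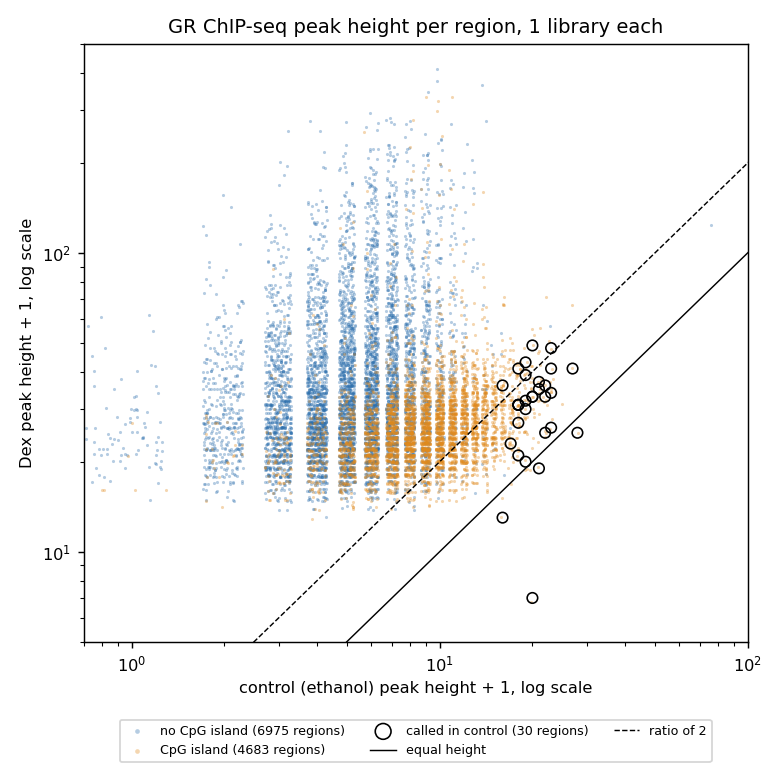
Peak height plus 1 of each of the 11658 regions in the control library (horizontal, log scale) and the Dex library (vertical, log scale), 1 point per region with small random jitter, coloured by CpG island, with the 30 control-called regions circled. Most points lie above the dashed line of a ratio of 2, and the circled regions lie near the lines at control heights of 15 to 27.

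The highest Dex signal lay at genes long known to respond to glucocorticoids and at several others. The highest region of all, with a Dex height of 410 against 9 in control, lay inside Klf13, a zinc finger transcription factor of the Krüppel-like family (chr1:125885819-125887427, 27478 bp from its start). Next came a region inside Zbtb16, a zinc finger repressor (chr8:51647642-51649176), with heights of 375 in Dex and 9 in control. Regions upstream of Klf9 (chr1:248187677-248189183) and of Per1, a repressor of the circadian clock (chr10:55425917-55427527, also assigned to Vamp2), both reached 330 in Dex, against 8 and 10 in control. A region inside Cdkn1a, the cell cycle inhibitor p21 (chr20:8595440-8597397), stood at 322 in Dex and 9 in control. The other regions of the 12 highest with a gene lay upstream of Armc12 (298 in Dex, 9 in control), downstream of Arrdc2 (293 and 5; also assigned to Kcnn1), downstream of F3, which encodes tissue factor (281 and 6), at -93 bp from the start of Plekha7, an adherens junction protein (278 and 7), inside Ddc, aromatic amino acid decarboxylase (275 and 7), upstream of Crispld2 (272 and 4), and inside Bcl2l1, which encodes the survival factor Bcl-xL (271 and 5). Their log2 ratios ran from 4.90 at Armc12 to 5.77 at Crispld2. The Armc12 region also lay upstream of the start of Fkbp5, to which it was not assigned. Among the 25 highest regions by Dex height, 10 had no assigned gene. The highest of these, chosen after its values were seen, lay at chr3:170731057-170731788 with heights of 363 in Dex and 13 in control.

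**Figure D2:**
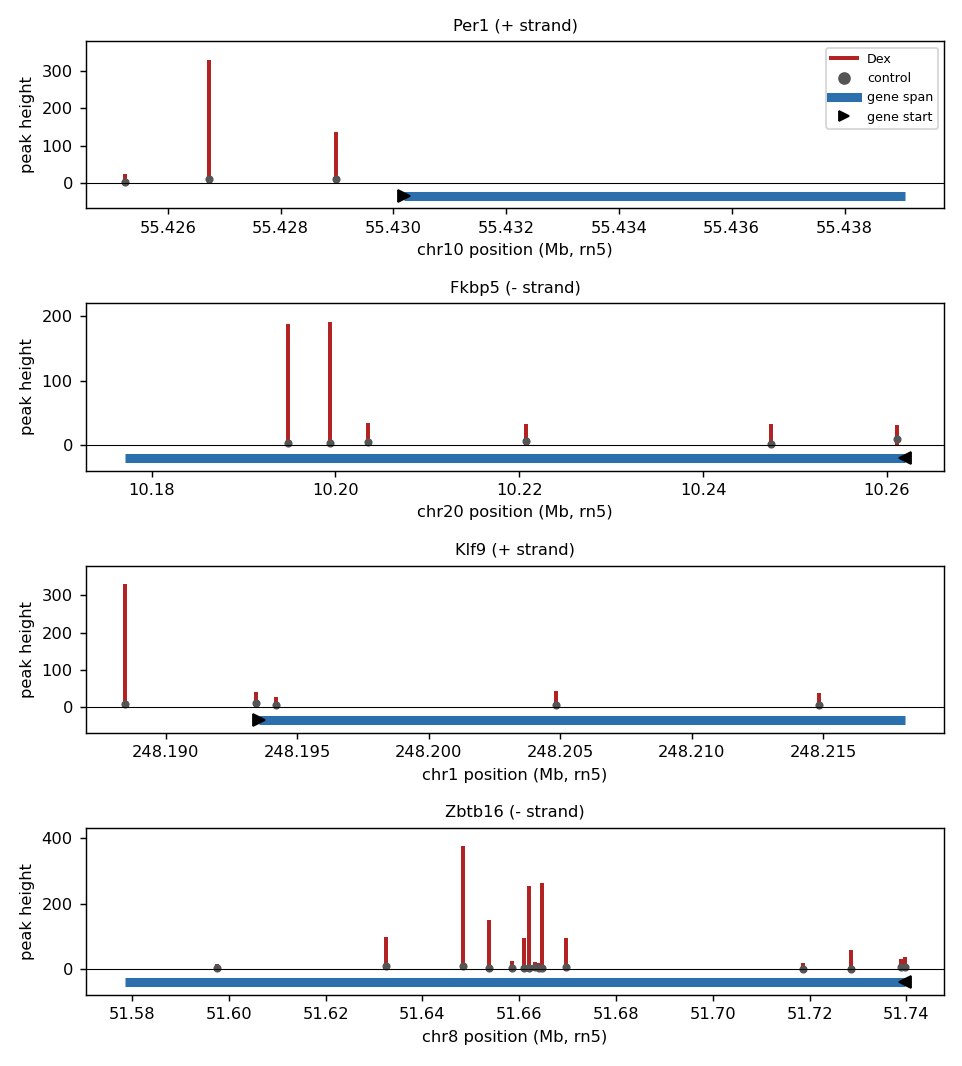
Dex peak heights (red lines) and control peak heights (grey points) of the regions assigned to Per1, Fkbp5, Klf9 and Zbtb16 along their rn5 positions in Mb, with the gene span in blue and the gene start as a black arrowhead. The highest regions lie upstream of Per1 and Klf9 and inside Fkbp5 and Zbtb16, at Dex heights of 330, 330, 191 and 375.

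Signal called without added hormone was confined, among the calls, to CpG islands. Without input heights, GR binding cannot be told apart here from other pull-down. Of the 280 regions with a control height of 15 or more, called or not, 273 overlapped a CpG island. All 30 control-called regions overlapped a CpG island (100%, exact 95% interval 88.4 to 100%), and 27 of the 30 lay within 1 kb of a gene start (90.0%, 73.5 to 97.9%). Their median height was 19 in control and 31.5 in Dex. The highest control-called region with a gene lay 249 bp inside Slc25a36, a mitochondrial nucleotide carrier (chr8:104441494-104442206), with 27 in control and 24 in Dex. It was followed by regions at the starts of Rexo4 (26 in control, 40 in Dex), Snrpa1, which encodes a spliceosome protein (22 and 33), Nup54, which encodes a nuclear pore protein (22 and 47), and Pdrg1 (22 and 25). The Dex height was greater at Rexo4, Snrpa1, Nup54 and Pdrg1 as deposited, but their log2 ratios centred on the CpG-island regions were below 0. Centred on the regions called in both, the log2 ratios of Rexo4, Snrpa1 and Pdrg1 were below 0. At Slc25a36 the direction turned with the average height in place of the peak height. The single region at a ratio of 0.5 or less as deposited, at chr17:35836135-35836430, was called in control alone. The table places it inside Foxc1, a forkhead transcription factor, but 24874 bp from its start, and this placement was not checked further. The region had heights of 19 in control and 6 in Dex, a log2 ratio of -1.51. The other region called in control alone lay nearest to Mir760 (15 in control, 12 in Dex).

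Regions of low and high Dex height differed in where they lay. By the nearest assigned gene, 49.8% of regions (48.9 to 50.7%) lay in a gene, 18.5% (17.8 to 19.2%) upstream, 4.72% (4.34 to 5.12%) downstream, and 27.0% (26.2 to 27.8%) had no assigned gene. A CpG island was overlapped by 40.2% of regions (39.3 to 41.1%), and 32.8% (31.9 to 33.6%) lay within 1 kb of a gene start. Among regions with a Dex height of 20 to 29, 51.7% overlapped a CpG island (50.4 to 53.1%), against 7.56% (6.12 to 9.22%) at 50 to 99 and 6.20% (4.05 to 9.02%) at 100 to 199. The share within 1 kb of a gene start was 41.9% (40.6 to 43.3%), 6.54% (5.20 to 8.11%) and 6.70% (4.46 to 9.60%) in these classes. The share with no assigned gene was 22.7% (21.5 to 23.8%), 37.0% (34.3 to 39.9%) and 35.2% (30.6 to 40.1%). In the highest class, 200 or more with 70 regions, 11.4% overlapped a CpG island (5.07 to 21.3%). There 2.86% lay within 1 kb of a gene start (0.35 to 9.94%) and 40% had no assigned gene (28.5 to 52.4%). Regions with a CpG island had a median height of 24 in Dex and 8 in control, and the other 6975 regions 30 in Dex and 4 in control. The median log2 ratio was 1.52 with a CpG island and 2.70 without. As deposited, 85.0% of regions with a CpG island and 99.1% of the others stood at a ratio of 2 or more. Centring on CpG-island regions sets their own median log2 ratio to 0 by construction. After it the shares were 7.03% and 59.4%, and the low share of CpG-island regions follows from that choice.

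**Figure D3:**
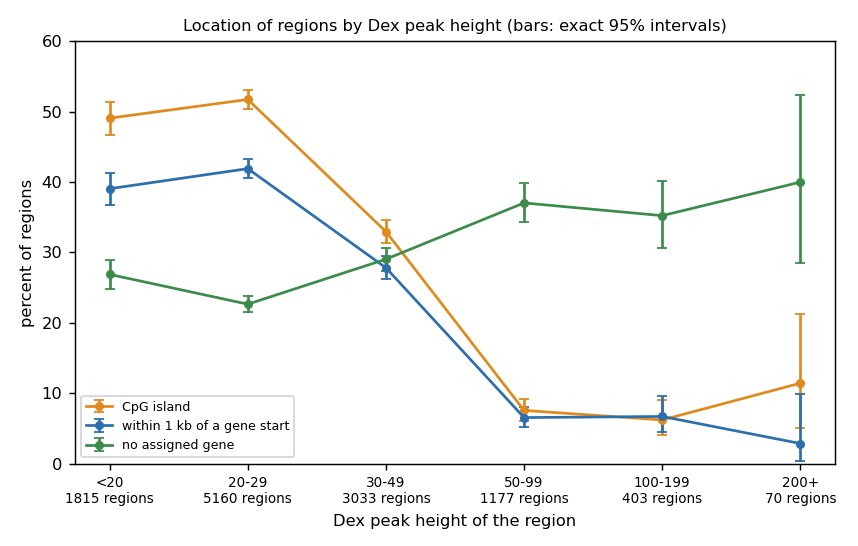
Percent of regions (vertical) that overlap a CpG island, lie within 1 kb of a gene start or have no assigned gene, by Dex peak height of the region (horizontal classes, with the number of regions), with exact 95% intervals of counting error. The CpG island share is 51.7% at heights of 20 to 29 and 7.56% at 50 to 99.

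Regions were assigned to 7080 genes, of which 7079 had a Dex-called region and 47 a control-called region. A single region was assigned to 4684 genes, and 217 genes had 5 or more. Of the 11658 regions, 2171 were assigned to more than 1 gene, so a region beside a named gene can belong to its neighbour.

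Nearly all canonical GR targets carried Dex-called regions. Of the 22 genes of this list, 20 were listed, each with a Dex call and none with a control call, and Angptl4 and Anxa1 were not listed. The median height of the 20 was 93 in Dex, above that of all 10000 length-matched random lists (median of these 26.5), and their median log2 ratio was 4.09, against 1.84 over all listed genes. Besides Zbtb16, Klf9, Per1 and Cdkn1a, high Dex peaks stood at Zfp36, an mRNA decay factor (193 in Dex, 4 in control), at Fkbp5, a co-chaperone of GR, which had 6 regions inside the gene (chr20:10198726-10200049 the highest, 191 and 3), and at Klf15 (175 and 7). Regions at Bcl6 (108 and 8), Lcn2 (102 and 3), Mt2A, a metallothionein (96 and 4), Errfi1 (90 and 5), Glul, which encodes glutamine synthetase (76 and 6), Sgk1, a kinase induced by glucocorticoids (66 and 6), Dusp1, a MAP kinase phosphatase (63 and 4), Nfkbia, the inhibitor of NF-kappa-B (61 and 3), and Ddit4, an inhibitor of mTOR (40 and 6), followed in order of Dex height. The lowest Dex heights in the list were at Pdk4 (30 and 8), Cebpd (28 and 10) and Ptgds (23 and 3). The Dex height at Cebpd was greater as deposited, but its log2 ratio centred on CpG-island regions was below 0. For Fkbp5, the heights above cover its assigned regions only. Higher regions lay upstream of its start, beyond the range of assignment. They were the Armc12 region (chr20:10301748-10303087, 298 and 9) and a region with no assigned gene (chr20:10290832-10291882, 278 and 6). The latter was chosen after its values were seen. Whether these regions belong to Fkbp5 was not tested. Tsc22d3, which encodes GILZ, had 1 region with 55 in Dex and 2 in control, which the table places on chr3, although Tsc22d3 is X-linked in mammals, so the identity of this locus is uncertain.

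Most members of the hypertrophy, sarcomere, calcium handling, cardiac transcription factor and fuel metabolism lists were listed, from 56.5% (fuel metabolism) to 75% (transcription factors). For scale, 34.7% of protein-coding genes and 58.3% of the 12 housekeeping genes were listed. A listed gene nearly always had a Dex call (7079 of 7080). Some genes, such as Gata4, are in more than 1 list, so the lists are not independent. Of 30 genes of hypertrophy and its signalling, 22 were listed. The highest were Myh7, the slow myosin heavy chain of the fetal gene programme, with 192 in Dex and 5 in control at chr15:37546137-37546955, upstream at -3858 bp from its start, then Ankrd1, a stretch-responsive repressor (130 and 9), Igf1r, the IGF-1 receptor (90 and 10), and Gata4 (69 and 5). Their median Dex height of 33 lay at percentile 92.2 of the random lists, at 99.96 with summed heights and at 58.9 once regions with a CpG island were left out. Of 22 sarcomere genes, 15 were listed, among them Ldb3, a Z-disc protein (104 and 6), Tpm1, tropomyosin (76 and 8), and Myl4, the atrial light chain (74 and 5). Their median of 42 lay at percentile 99.8, and at 85.4 once regions with a CpG island were left out. Of 20 genes of calcium handling and ion channels, 14 were listed, led by Cacna1c, the L-type calcium channel subunit, with 13 regions (highest 160 and 9), Atp2a2, the SERCA2 calcium pump (143 and 4), Kcnq1 (142 and 4) and Kcnh2 (113 and 4), both potassium channels of repolarisation. Their median of 52 lay at percentile 99.6, and at 94.8 without CpG-island regions. Without those regions the medians of the hypertrophy, sarcomere and calcium handling lists were 35, 42 and 56, so none fell. Their random lists then had medians of 33.5, 33 and 36, against 28.5, 28 and 30 with all regions. Ryr2, the calcium release channel, and Gja1, connexin 43, were not listed.

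Of 16 cardiac transcription factors, 12 were listed, with the highest Dex peaks at Myocd, myocardin (111 and 5), Gata4, Mef2c (40 and 3) and Mef2a (38 and 7), and a median of 33 at percentile 83.3 (96.9 with summed heights, 46.2 without CpG-island regions). Of 23 genes of cardiac fuel metabolism, 13 were listed, led by Plin5, a lipid droplet protein (192 and 3, at chr9:9951189-9951714, 8448 bp from its start and downstream of it), Slc2a1, the GLUT1 glucose transporter (108 and 4), Ppara (79 and 2) and Esrrg (74 and 5). Their median of 38 lay at percentile 98.5, and at 75.7 when only regions in the promoter range were used. The circadian clock list had 9 of 14 members listed, led by Per1, Tef (153 and 7), Cry2 (82 and 8) and Per2 (76 and 5), with a median of 68 at percentile 99.97. In the muscle atrophy list 8 of 10 were listed, led by Sesn1 (221 and 5), Foxo3, which had 11 regions (highest 216 and 7), Klf15 and Ddit4. Their median of 35.5 lay at percentile 93.2, and at 97.6 when the heights of a gene's regions were summed. The cell survival and death list had 9 of 14 listed and a median of 28 at percentile 58.7, with high peaks at Bcl2l1, at Bcl2l11, which encodes the pro-apoptotic factor Bim (173 and 5), at Bnip3 (157 and 8) and a lower one at Mcl1 (50 and 4).

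Genes of GR machinery were listed for 11 of 14, with a median of 32 at percentile 73.9. They included Fkbp5, Hsd11b1, which regenerates active glucocorticoid (92 and 4), and Ncoa1, a coactivator (44 and 4). Of 21 inflammation genes 8 were listed, led by Nfkbia, Nfkb1 (58 and 2), Stat3 (53 and 9) and Nfkb2 (24 and 7). Their median Dex height of 22.5 lay low, at percentile 7.34, whereas their median log2 ratio of 2.65 lay high, at 96.6. With the heights of a gene's regions summed, the median lay at percentile 83.8. Il6, Tnf and Ccl2, cytokine genes repressed by glucocorticoids in many cells, were not listed.

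Few liver GR targets, fibroblast markers and immune markers were listed. Of 12 liver GR targets 1 was listed, G6pc, with a region downstream (55 and 4). Tat and Pck1, targets of GR in liver, were not listed. Of 11 fibroblast markers 1 was listed, Ddr2 (24 and 3), and of 9 immune markers 1, Cd68 (28 and 8). Of 8 smooth muscle and pericyte markers 2 were listed, Mylk (116 and 8) and Cspg4 (66 and 7). Of 10 endothelial markers 4 were listed, Pecam1 (56 and 4), Erg (50 and 2), Eng (33 and 3) and Kdr (26 and 6), with a median at percentile 87.3 (96.8 with summed heights, 62.7 without CpG-island regions). Of 12 housekeeping genes 7 were listed, among them Actb (72 and 10), Ywhaz (37 and 10) and Rplp0 (26 and 11). The median of the 7 was 26, at percentile 47.3 (93.8 in the promoter range, 90.9 with summed heights). The log2 ratio at Rplp0 fell below 0 when centred on CpG-island regions. By the number of members listed, the percentile among random lists of protein-coding genes was 100 for canonical GR targets and the hypertrophy list, 99.96 for GR machinery, 99.9 for sarcomere genes, calcium handling and cardiac transcription factors, 99.7 for muscle atrophy, 98.6 for cell survival and the circadian clock and 98.4 for fuel metabolism. It was 94.9 for housekeeping genes, 64.2 for endothelial markers, 63.4 for inflammation, 30.7 for smooth muscle and pericyte markers, 7.21 for immune markers, 3.58 for fibroblast markers and 2.43 for liver GR targets. The comparison by number listed was not matched on gene length, so it cannot separate gene length from other differences between the lists. By the median log2 ratio in place of the height, the percentile was 100 for canonical GR targets, 99.4 for sarcomere genes, 98.4 for the hypertrophy list, 97.8 for calcium handling, 95.6 for endothelial markers and for muscle atrophy, 93.5 for the circadian clock, 90.9 for GR machinery, 84.7 for cardiac transcription factors, 79.1 for fuel metabolism, 65.8 for housekeeping genes and 33.8 for cell survival.

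**Figure D4:**
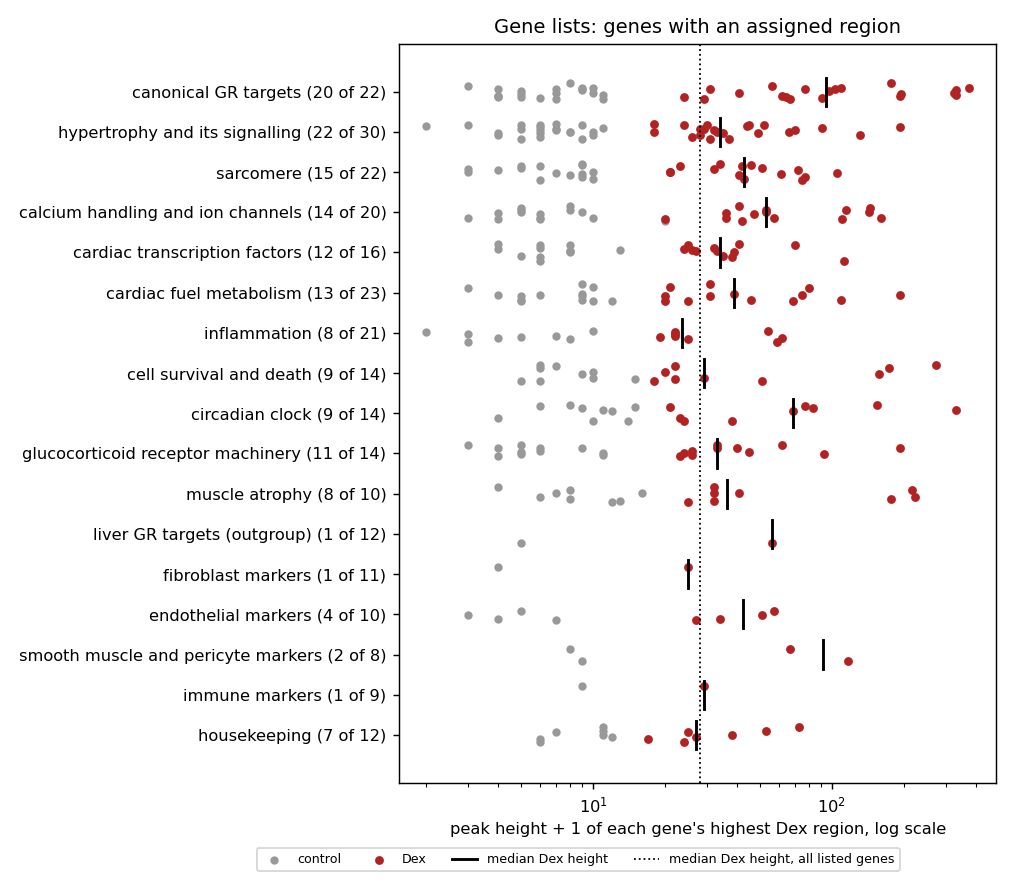
Peak height plus 1 (log scale) of each listed gene's region with the highest Dex peak, in control (grey) and Dex (red), for the 17 gene lists, with the number of members listed of all members, the median Dex height of the list (black bar) and of all listed genes (dotted line, at a height of 27). The canonical GR targets have the highest median, 93, of the lists with 3 or more listed members.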

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

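The CpG-island centring, the removal of CpG-island regions and the percentile by number of members listed were chosen after the data were seen. With a stricter call (1.5 times the lowest called height) the calls in control and in both numbered 2 each and in control only 0. When a control height of 15 or more counted as a call they numbered 280, 279 and 1, and Dex calls changed by less than 1.5 times under both. Leaving out X moved no count of calls by over 1.5 times. The count at a ratio of 2 or more was 5780 among regions whose higher height reached the median, where fewer regions enter, and 4469 when centred on CpG-island regions, and stayed within 1.5 times of 10894 under the other settings. The count at 0.5 or less was 2 when centred on regions called in both, 0 with the height filter and at a ratio of 3, and 115 when centred on CpG-island regions. The median log2 ratio was 2.31 with average heights, 1.62 and 2.36 with pseudocounts of 5 and 0.1, 1.45 centred on regions called in both, 2.73 with the height filter and 0.65 centred on CpG-island regions. Among the regions at or above the median Dex height, 32.8% lay in the promoter range, 48.8% in a gene, 29.5% on a CpG island and 29.6% had no assigned gene. Distances of 1 kb and 10 kb in place of the promoter range gave 32.8% and 48.2%. Genes with a Dex region numbered 4685 with the promoter range alone, and genes with a control region 29 with the nearest gene alone.

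The canonical GR targets stayed at or above percentile 99.96 by height and by number listed in the settings run here, and the circadian clock list at or above 98.3, though by the median log2 ratio the clock list stood at 93.5. The hypertrophy list moved across percentile 95 to 97.1 against unmatched lists, 98.1 in the promoter range, 99.96 with summed heights and 100 by number listed, and stood at 58.9 without CpG-island regions. Under that removal cardiac transcription factors stood at 46.2, endothelial markers at 62.7, GR machinery at 85.1, the sarcomere list at 85.4, calcium handling at 94.8 and fuel metabolism at 97.52, while inflammation stood at 13.1, cell survival at 90.1 and muscle atrophy at 99.3. In the promoter range fuel metabolism stood at 75.7, inflammation at 2.67, cell survival at 34.9, GR machinery at 85.5, cardiac transcription factors at 91.5, housekeeping at 93.8, muscle atrophy at 95.2, the sarcomere list at 99.9 and calcium handling at 99.96. With summed heights cardiac transcription factors stood at 96.9, muscle atrophy at 97.6, endothelial markers at 96.8, inflammation at 83.8, cell survival at 88.5, housekeeping at 90.9, GR machinery at 94.6, the sarcomere list at 98.8, fuel metabolism at 99.7 and calcium handling at 99.98. Against unmatched lists inflammation stood at 5.74, housekeeping at 37.7, cell survival at 55.4, GR machinery at 87.3, endothelial markers at 90.7, cardiac transcription factors at 91.8, muscle atrophy at 92.5, fuel metabolism at 98.4, the sarcomere list at 99.7 and calcium handling at 99.98. By number listed cardiac transcription factors stood at 99.92, cell survival at 98.6, GR machinery at 99.96 and muscle atrophy at 99.7. The endothelial list in the promoter range and the housekeeping list without CpG-island regions kept fewer than 3 members and gave no value.

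Of the 80 named log2 ratios, none changed sign with either pseudocount. That outcome was fixed in advance, because the sign depends only on which of the heights is greater. With average heights Slc25a36 turned to 0.76. Centred on regions called in both, Rexo4 stood at -0.12, Snrpa1 at -0.16 and Pdrg1 at -0.55. Centred on CpG-island regions, these stood at -0.92, -0.96 and -1.35, Nup54 at -0.46, Cebpd at -0.13 and Rplp0 at -0.35. The cause of these moves was not tested beyond the shift that each centring makes. No paired analysis was possible because each group has 1 library. The input filter and the response element search were not run. With 1 library per group and no depth given, the data cannot separate a difference between treatments from a difference between libraries.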

Other observations

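The genes and the region singled out here, and both tests on CpG islands, were chosen only after the result was seen, and the tests on X were set after the low number of regions there, but before their own results, was seen. Among the genes with the most assigned regions, Tns1, which encodes the focal adhesion protein tensin 1, had 24 regions (highest 257 in Dex, 5 in control). It was followed by Zmiz1 with 17, Zbtb16 with 15, Cux1 with 14, and Cacna1c, the integrin gene Itga9 and Rbm20, a splicing regulator of titin, with 13 each. Nuak1 had 12 regions, and Foxo3 and Sulf2 had 11 each. Most of these genes are long, for example 206569 bp for Tns1 and 620000 bp for Cacna1c, but Nuak1 spans 68978 bp and Sulf2 81878 bp. The region with the highest control height, at chr20:29291315-29291594, had 75 in control and 123 in Dex, was not called in control and had no assigned gene. Of the 280 regions at or above the lowest called control height, 250 were not called in control.

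Regions with a CpG island had a median log2 ratio lower by 1.18 than the others, with control heights of 8 against 4. The tables argue against lower Dex heights as the whole cause, because among regions with a Dex height of 20 to 29 the difference was -0.84 (95% bootstrap interval over regions -0.90 to -0.80). At a fixed Dex height this compares control heights alone, so it restates their difference, and at Dex heights of 100 or more, with 33 CpG-island regions, the interval reached 0.13 and excludes nothing, after which the bound of the test was narrowed to lower heights. A candidate explanation that stays open is pull-down at open promoters in both libraries: control and Dex heights correlated across CpG-island regions with a Spearman rho of 0.32, and with 0.17 across the others (regions are not independent replicates). Binding of GR at promoters without added hormone would give the same correlation, and input heights, which could separate these, were not used here.

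X held few regions, 104, or 0.68 per Mb up to its last region, against 2.85 (chr4) to 7.59 (chr10) per Mb on the autosomes. A signal per site on X of 0.5 times that elsewhere, as from a lower copy number, predicts equal densities once autosomal heights are cut at 2 times the X height. X regions with a height of at least 20 were 0.54 times as dense (0.42 to 0.67) as autosomal regions of at least 40. That interval covers counting error over pooled autosomes and not the spread between chromosomes. The lowest autosome at that height, chr4, came near, at 0.59 per Mb against 0.49 on X. With X cut at 15 and 30, X had 0.68 and 0.21 per Mb, and chr4 1.10 and 0.31. X thus lay below the lowest autosome, but as a single chromosome near it X cannot decide this explanation. The mean control height of regions without a CpG island on X was 0.75 (0.65 to 0.88) of that on autosomes. Regions with no assigned gene were 0.22 times as dense on X (0.15 to 0.30). This cannot decide whether fewer genes on X were the cause, because such regions can still lie near genes, beyond the distance of assignment. Among the autosomes, chr4 had the fewest regions per Mb and also the fewest with no assigned gene, at 0.75 per Mb. Mapping to repeats or gaps on X and a real lack of GR binding there also stay open and were not tested.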
